A study of Limosilactobacillus reuteri subsp. reuteri F275 with 13 samples.

How the data were processed

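The data are 13 two-colour microarrays on which RNA of Limosilactobacillus reuteri subsp. reuteri F275 was hybridised as 6 RNA extracts in a loop design, per the labels. Cells were quenched in cold methanol buffer, total RNA was extracted with phenol and chloroform and treated with DNase, and cDNA carrying aminoallyl groups was coupled to Cy3 or Cy5, per the labels' protocols. The scanned spots were quantified in ImaGene with Cy3 as channel 1 and Cy5 as channel 2, per the file headers, and the deposited scanner files hold for each of 45220 spots the signal and local background intensity of each channel on a linear scale, not normalized. The submitters' processing notes name limma with no version or role. The deposited value table holds 1 log2 ratio per probe spot and array. Set against the scanner values, it is the log2 of Cy3 over Cy5 after subtraction of the mean background, with no centring: at least 99.993% of the values of each column lay within 0.001 of that, and the column medians ran from 0.00609 to 0.841. Its direction is therefore opposite to the ratios used here, and its sign was turned. Slide and scan date are not given in the sources used here, so neither was tested as a batch.

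Each array's group and dye assignment was taken from its labels. The ORF is the unit of measurement: 43803 probe spots gave 9308 probes with 4 to 9 spots each and 1683 ORFs with 1 to 6 probes each (1379 ORFs with 6). None of the 1683 identifiers was found among the 2047 genes of the reference gene table of strain TD1, so 0 of the 20 gene lists fixed beforehand (cobalamin synthesis, propanediol use, cysteine and methionine metabolism and others) could be tested, and no pathway is named. The rule fixed beforehand for named genes, the largest rises and falls among calls whose extract levels do not overlap, was cut to the first 2 rises and first 2 falls of the exponential comparison, because identifiers without gene names are printed for only 4 ORFs. All 108 higher and 9 lower calls of that comparison met the condition on overlap, so it removed none. Runs of at least 3 consecutive identifiers called in the same direction were counted after seeing the data, and set against 10000 random permutations of the calls over the positions. The runs described were the longest and the one with the highest absolute median in each comparison, together with some further runs picked after their values were seen.

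Signal means and background medians were read in R 4.3.3 and processed in limma 3.58.1. Background was corrected with normexp (offset 50) on all spots, and each array was normalized by loess with its 1417 control spots at weight 0, with no step between arrays. The plan assumed Agilent Feature Extraction columns. The files are ImaGene's, so its Signal Mean and Background Median were used. Its flags, which mark empty and misshapen spots, were not used to remove spots. Flags were read for the Cy3 channel only, where 60.7% to 71.9% of probe spots per array carry flag 0. Spots with flag 0 in that channel are called unflagged here. These flag and empty-spot columns are scores written by ImaGene, per the file headers. Spots of a probe were averaged and an ORF's value was the median over its probes. A probe was called above background on an array and channel when at least 50% of its spots were not marked empty by ImaGene. No spot was saturated. All choices of test, comparison and alternatives were fixed before the data were examined unless said otherwise.

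The test had 2 stages. For each ORF the log2(Cy5/Cy3) of the 13 arrays was fitted by least squares as the level of the Cy5 extract minus the level of the Cy3 extract plus a dye effect of that ORF, which gave 1 relative log2 level for each of the 6 extracts. The 6 levels were then tested in limma with a mean per group and empirical Bayes moderation, and p-values were adjusted by the Benjamini-Hochberg method over the 1683 ORFs of a comparison, with a threshold of 0.05. All groups shared 1 estimate of spread, which came from the exponential groups alone, with 2 extracts each. Errors of log2 changes are standard errors of this fit. The procedure was tested on simulated data with 200 of 1683 ORFs changed: in the exponential comparison it recovered 62.6%, 91.8% and 97.1% of changes of 0.5, 1 and 2 on the log2 scale with 3.35% false calls, and in the early stationary comparison 24.6%, 79.4% and 94.9% with 2.73% false calls. With no change simulated, each comparison made a mean of 0.05 to 0.1 calls. The simulation gave the early stationary extracts the same spread as the exponential ones, drew the ORFs independently and took every array label as true. These rates therefore do not test those assumptions.

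Array J departed from its label in the prediction from the other arrays. It was kept in the fit, and the counts of the main fit were repeated without it. Of the alternatives, only arrays as replicates, the omission of each exponential extract and the F number as a block were also run without it. The alternatives were no background subtraction, median centring, Aquantile normalization between arrays, only probes above background (8652 of 9308), the mean over probes, no dye effect, arrays as replicates, the deposited values with each column centred on its median, no array N, a minimum change of 1 on the log2 scale, each array and each exponential extract left out, and the F number as a block. Added after seeing the data were the use of unflagged spots only, of the 4 direct exponential arrays only, and several alternatives combined with the removal of array J. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.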

Results

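RNA of Limosilactobacillus reuteri subsp. reuteri F275, a lactic acid bacterium of the gut that makes vitamin B12, was compared on 2-colour microarrays in a study of how the supply of amino acids affects vitamin production. There were 6 RNA extracts. 2 came from exponential-phase cultures with cysteine (CysExp F1 and F3), 2 from exponential-phase cultures without cysteine (NoCysExp F2 and F4), 1 from an early stationary culture with cysteine (CysEarlySta F3) and 1 from an early stationary culture without it (NoCysEarlySta F4). The labels write only "Cys" and "NoCys", read here with the study's title as with and without cysteine, and do not say what the F numbers stand for. Each of 13 arrays, named by letter, held 1 extract in Cy3 and 1 in Cy5, and the arrays were linked in a loop in which each extract met several others. On array N both channels held NoCysExp F2. The array carried 9308 probes for 1683 open reading frames (ORFs). The median spot signal per array was 736 to 996 in Cy3 and 697 to 865 in Cy5, over median local backgrounds of 490.5 to 502.5 and 485 to 507.5, and 83.3% to 93.8% of probes were above background in a channel. The number of extracts, not of spots, limits the precision. The files give ORF identifiers only and do not pair them with gene names, so at most 2 identifiers that rose and 2 that fell are printed, and the remaining ORFs are described by number, size of change and position in runs of consecutive identifiers.

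The arrays were first set against their own labels. Each array was predicted from the extract levels fitted to the other 12 arrays, and the SD over ORFs of the measured minus the predicted log2 ratio was 0.0810 to 0.338 for 12 of the 13 arrays. For array J, labelled CysEarlySta F3 in Cy3 and NoCysExp F2 in Cy5, it was 0.556, and its label ranked 12 among the 31 possible pairs of extracts. The labels of arrays A and B, which also hold NoCysExp F2, each ranked 3, and the label ranked first for 9 of the 12 arrays that hold 2 different extracts. With array J left out, it ranked first for all 11 others of these, and errors ran from 0.0707 to 0.162. Array N does not test its label, since every pair of equal extracts predicts a ratio of 0. On array N the SD of the log2 ratio was 0.0776. The 2 CysExp extracts differed by an SD of 0.185 over ORFs. The 2 NoCysExp extracts differed by 0.301, or by 0.221 without the array labelled J. Array J was kept under its label, and for each comparison the number of ORFs called is also given without it.

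**Figure D1:**
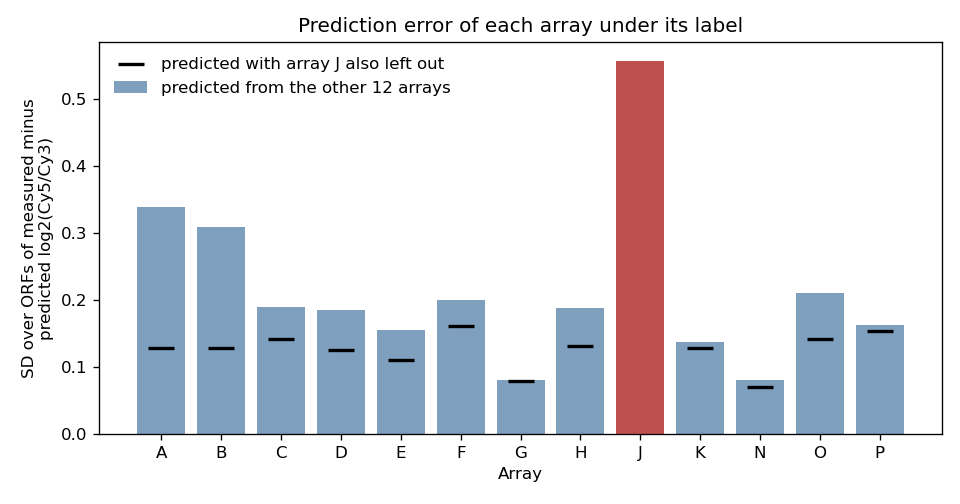
Prediction error of each of the 13 arrays under its label, as the SD over 1683 ORFs of the measured minus the predicted log2(Cy5/Cy3), for predictions from the other 12 arrays (bars) and with array J also left out (black marks). Array J lies at 0.556, and the other 12 arrays lie between 0.0810 and 0.338 with array J in the fit and between 0.0707 and 0.162 without it.

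The first comparison asked what changed in exponential phase when cysteine was absent, with 2 extracts per medium. Of 1683 ORFs, 108 were higher and 9 were lower without cysteine. The median log2 change was 1.03 among the higher ORFs and -0.66 among the lower ones, and 57 rose and 2 fell at least 2-fold (46 and 2 without array J). LR1RLRE00827 rose by 5.19 ± 0.52 on the log2 scale (SE, n = 2 extracts per medium; adjusted p = 0.0155, limma with Benjamini-Hochberg adjustment), and LR1RLRE00828, the next identifier, rose by 5.07 ± 0.63 (adjusted p = 0.0214, limma). On all 4 arrays that hybridised exponential-phase extracts of the 2 media to each other, LR1RLRE00827 was higher without cysteine, by 4.42 to 6.08, and LR1RLRE00828 by 4.08 to 6.12. Their levels in exponential phase with cysteine lay near background: in the 2 CysExp extracts, 66.7% and 80% of the probe readings of LR1RLRE00827 were above background and 45.8% and 46.7% of those of LR1RLRE00828, against 100% in the other 4 extracts. At least 1 probe of each was above background in 3 of the 4 readings of CysExp F1 and in 5 of the 5 of CysExp F3. The size of both rises therefore depends on how background is treated: without background subtraction they were 3.04 and 3.02 and did not pass, and from the deposited values they were 6.69 and 6.67. LR1RLRE01446 fell by 2.43 ± 0.33 (adjusted p = 0.0254, limma), and LR1RLRE00774 fell by 1.51 ± 0.18 (adjusted p = 0.0206, limma), both with all probe readings above background. These 2 falls also did not pass with no background subtraction (adjusted p = 0.0737 and 0.0582, limma), and none of the 4 ORFs passed without CysExp F1 or without CysExp F3 (adjusted p = 0.119 to 0.202, limma).

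**Figure D2:**
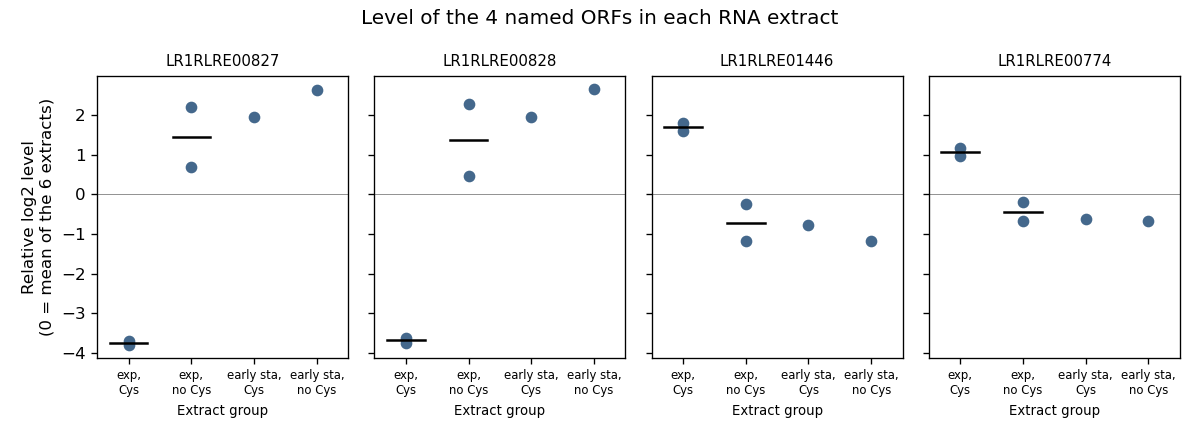
Relative log2 level of the 4 named ORFs in each of the 6 RNA extracts (points; 0 is the mean of the 6), with the mean of the 2 extracts of each exponential group as a line. LR1RLRE00827 and LR1RLRE00828 stood 5.19 and 5.07 higher without cysteine in exponential phase. The 4 ORFs were chosen among calls whose exponential levels do not overlap between the 2 media, a condition that all 108 higher and 9 lower calls met.

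Many of the ORFs that changed in exponential phase had consecutive identifiers. Of the 117 called ORFs, 85 lay in 13 runs of at least 3 neighbours changed in the same direction, where permuted positions gave a mean of 1.25 and a maximum of 13 (one-sided permutation p = 0.0001 and 0.0001 after Benjamini-Hochberg adjustment over 12 such tests, the smallest that 10000 permutations can give). Without array J, 83 of 116 calls lay in runs. The number in runs moved with the number of calls: it was 0 without CysExp F1, 55 without CysExp F3, 130 without NoCysExp F4, 27 with no background subtraction and 41 at a minimum change of 1 on the log2 scale. A run of 24 ORFs was higher throughout, with a median log2 change of 1.07 and a range of 0.72 to 1.33 over its members. A group of 3 runs lying close together, of 9, 15 and 3 ORFs, had medians of 0.92, 1.04 and 0.71. A run of 4 ORFs had the highest median, 1.84. A run of 3 ORFs was the only one among the 9 lower ORFs, with a median of -0.67. The 4 direct arrays correlated by 0.73 to 0.84 over ORFs, which are not independent replicates.

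The exponential calls came from limma on 6 extract levels, and 104 ORFs were higher and 12 lower without array J, with 102 calls shared. No ORF was called without CysExp F1 (319 at an unadjusted p under 0.05), 72 were called without CysExp F3, 198 without NoCysExp F4, and 52 with no background subtraction, while 99 were called without both CysExp F1 and array J. Nothing in the labels says whether the extracts came from separate cultures, so the p-values measure only the spread between these extracts, which can be technical.

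The second comparison asked the same of early stationary phase, with 1 extract per medium. Without cysteine, 105 ORFs were higher and 116 were lower. The median log2 change was 0.67 among the higher and -0.65 among the lower ORFs, and 21 rose and 23 fell at least 2-fold (25 and 27 without array J). The ORFs in a run of 6 were all lower, and 5 of them fell far: their median change was -4.57, with a range of -4.74 to -4.38. A run of 4 ORFs, the one with the highest median in exponential phase, was higher by a median of 2.99, with a range of 2.90 to 3.14. The longest run held 9 ORFs with a median rise of 0.58. In all, 64 of the 221 calls lay in 14 runs (permuted mean 2.62, maximum 18; one-sided permutation p = 0.0001, the smallest possible), and 72 of 264 without array J. None of the 4 named ORFs passed the test in this phase: the log2 change was 0.68 ± 0.74 (SE) for LR1RLRE00827, 0.72 ± 0.89 for LR1RLRE00828, -0.40 ± 0.47 for LR1RLRE01446 and -0.04 ± 0.26 for LR1RLRE00774.

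The 2 direct arrays, E and K, which held the same 2 extracts with the dyes exchanged, correlated by 0.928 over ORFs. The test borrows its spread from the exponential extracts, so the 2 lone extracts are assumed to vary like those, and the contrast has no replicate check of its own. Without array J, 130 ORFs were higher and 134 lower, with 212 calls shared. With array J kept, the total was 106 without array A, 88 without array B and 108 with no background subtraction. Leaving out either CysExp extract removed nearly all calls with array J kept, but did not lower the total with array J left out. Leaving out either NoCysExp extract lowered the total only with array J left out.

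**Figure D3:**
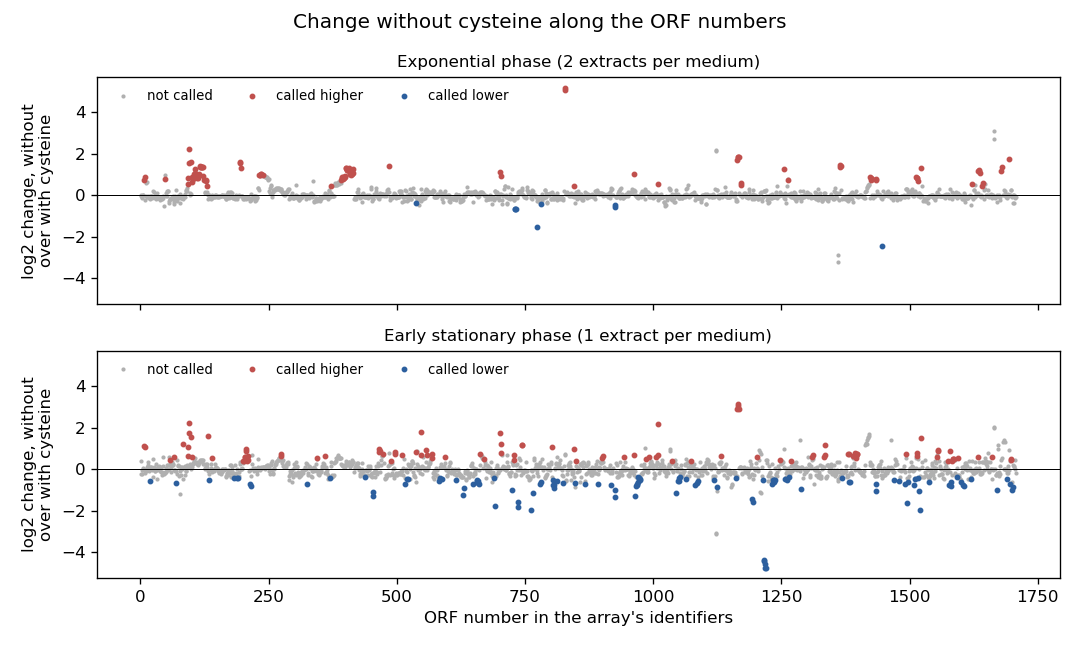
Log2 change without over with cysteine (vertical axes) against the ORF number in the array's identifiers (horizontal axis), in exponential phase (above, 108 ORFs called higher and 9 lower) and early stationary phase (below, 105 higher and 116 lower). Called ORFs in exponential phase fall in runs, the longest of 24 ORFs, and 5 neighbouring ORFs stand near -4.57 in early stationary phase.

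The third comparison asked whether the cysteine effect differed between the phases, as the difference of the 2 medium effects. It passed for 83 ORFs, 37 with a higher effect in early stationary phase and 46 with a lower one. In the 5 ORFs that fell far in early stationary phase, the effect in exponential phase was a median of 0.20, which did not pass, and the difference was -4.77, with a range of -5.00 to -4.58 (adjusted p = 0.0178, limma, for each of the 5). In the run of 4 ORFs that rose in both phases, the rise was greater in early stationary phase by a median of 1.22 (adjusted p = 0.0250 to 0.0481, limma). A run of 3 ORFs rose by a median of 1.58 in exponential phase, was at 0.24 in early stationary phase and differed by -1.33. For LR1RLRE00827 the difference was -4.51 ± 0.90 (SE; adjusted p = 0.0700, limma), and for LR1RLRE00828 it was -4.34 ± 1.09 (adjusted p = 0.0911, limma), so their effect was not shown to differ between the phases. Both ORFs lay near background in the CysExp extracts, so the sizes of these differences are uncertain.

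The 2 medium effects share no extract, but both include an F4 extract without cysteine set against an F3 extract with it. The labels do not say what the F numbers stand for. A difference that goes with them cannot be told apart from a cysteine effect common to both phases. Of the 108 ORFs higher in exponential and the 105 higher in early stationary phase, 21 were higher in both, where independent lists would share 6.74, and 2 of the 108 were lower in early stationary phase. Of the 9 and 116 lower ORFs, 3 were shared, against 0.620 for independent lists. Both tests divide by the same spread of each ORF, taken from the exponential extracts, so ORFs with a small spread are called more readily in both, which raises shared calls of the same and of opposite direction alike. Of the 108 ORFs higher in exponential phase, called or not in the other, 99 had a positive change in early stationary phase, with a median log2 change of 0.33 (92 of 104 without array J, median 0.31). The 2 log2 changes correlated by 0.254 over ORFs with a covariance of 0.0538, against -0.0311 and -0.00174 when no change was simulated. That simulation drew all extracts independently, so it holds no effect of a shared F number. Without array J the difference passed for 46 and 54 ORFs, with 76 calls shared. With array J kept, the total of 83 became 0 without array A (502 at an unadjusted p under 0.05 in limma) and 6 without array B. It was 26 without array D, 44 without array F and 43 without array G. It was 16 with no background subtraction, 23 with no dye effect and 147 from the deposited values. No ORF passed when either CysExp extract was left out, and more passed when either NoCysExp extract was left out. With array J left out too, some ORFs passed whichever exponential extract was left out.

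The fourth comparison asked what changed from exponential to early stationary phase. As the mean of both media, 329 ORFs were higher and 273 lower in early stationary phase, with 63 rises and 7 falls of at least 2-fold (91 and 10 without array J). With cysteine alone, 389 were higher and 309 lower, with 88 rises and 40 falls of at least 2-fold (114 and 49 without array J), the median log2 change being 0.63 among the higher and -0.50 among the lower ORFs. The longest run in the mean of both media held 27 ORFs, all higher, with a median log2 change of 1.35 and a range of 0.32 to 1.63. The median over this run was 1.73 with cysteine, where 26 of the 27 passed, and 0.98 without, where none passed with all arrays and 25 passed without array J. The 5 neighbouring ORFs that fell far without cysteine in early stationary phase rose with cysteine by a median of 5.56, with a range of 5.30 to 6.01 (adjusted p = 0.00216 to 0.00253, limma); both comparisons use the CysEarlySta F3 extract. A second run of 5 ORFs had the highest median in the mean of both media, 3.88, or 4.93 without array J. The run of 24 ORFs that rose without cysteine in exponential phase was also higher in early stationary than in exponential phase with cysteine, by a median of 0.68, with all 24 called, and was at -0.14 without cysteine, with none called. The first 2 of these comparisons subtract the same 2 CysExp extracts, and their log2 changes correlate by 0.366 over ORFs when no change is simulated, so these calls are not independent of the exponential ones. From exponential to early stationary phase with cysteine, LR1RLRE00827 rose by 5.72 ± 0.64 and LR1RLRE00828 by 5.63 ± 0.77 (SE; adjusted p = 0.00757 and 0.0106, limma), sizes that are uncertain because both lay near background in the CysExp extracts, and LR1RLRE01446 fell by 2.49 ± 0.41 and LR1RLRE00774 by 1.69 ± 0.23 (adjusted p = 0.0152 and 0.0102, limma).

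**Figure D4:**
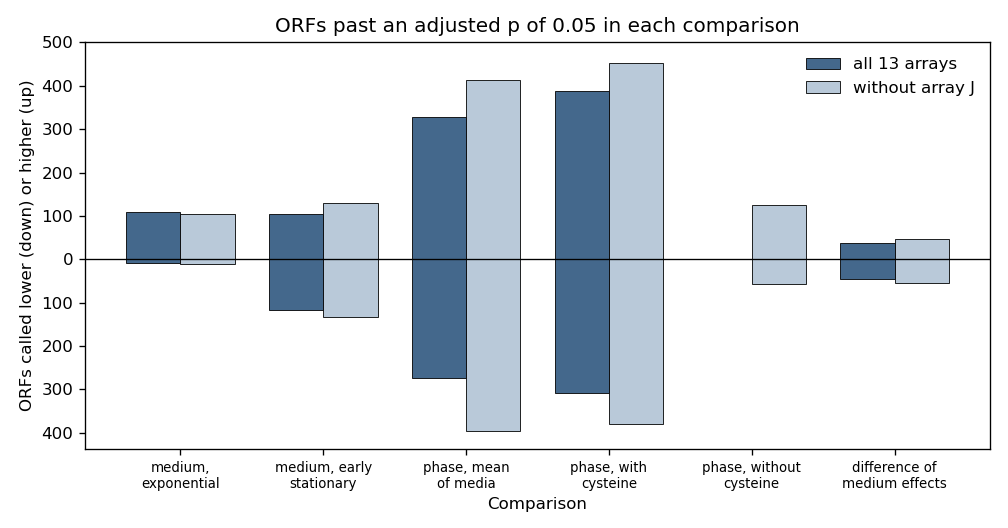
Number of ORFs past an adjusted p of 0.05 in each of the 6 comparisons, higher above the zero line and lower below it, with all 13 arrays (dark) and without array J (light). With all arrays 108 ORFs were higher and 9 lower without cysteine in exponential phase, and the phase comparison without cysteine moved from 1 call to 183 when array J was left out.

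Without cysteine, the phase comparison passed for 1 ORF with all arrays, which rose by 1.55 ± 0.07 (SE; adjusted p = 0.0252, limma) and changed by -0.06 with cysteine, which did not pass. On array P, which alone hybridised exponential and early stationary extracts without cysteine to each other, this ORF was higher in early stationary phase by 0.82. That ratio holds the ORF's dye effect and NoCysExp F4 only. The fitted value removes the dye effect and averages both NoCysExp extracts, so the 2 values are unlike measures. Without array J the fitted rise was 1.83 ± 0.15, a shift larger than the first SE, so that small SE understates the uncertainty. With all arrays, 331 ORFs had an unadjusted p under 0.05 in this comparison. Without array J, 126 ORFs were higher and 57 lower. The run with the highest median then was the second run of 5 ORFs, which rose by 5.52 (range 5.24 to 5.71) without cysteine and by 4.34 with cysteine. A run of 20 ORFs, part of the run of 27, rose by 1.22. Of the 452 and 126 ORFs higher in early stationary phase with and without cysteine in that fit, 116 were shared, against 33.8 for independent lists, and of the 379 and 57 lower ones 43 were shared, against 12.8, with the same common spread in both tests.

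The mean phase comparison passed for 414 and 395 ORFs without array J, with 601 calls shared, and for 320 in all without array B. With the F number as a block over the 2 pairs of extracts that share one, limma called 1 ORF there, or 2 without array J. That fit uses fewer extracts, and whether the numbers pair the extracts could not be checked. The comparison with cysteine passed for 452 and 379 ORFs without array J, with 688 calls shared. The phase count without cysteine moved with single arrays: it was 183 without array J, 3 without array E and 0 without array A, B, C, D, F, H or P. In the fits with 0 calls limma gave 173 to 354 ORFs at an unadjusted p under 0.05. All of these fits but the first kept array J. Without array J the residual SD of the arrays about the fit was 0.0878, against 0.172 with it. With array J kept, the count also moved when any 1 exponential extract was left out. With array J left out too, calls remained whichever exponential extract was left out.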

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

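The tests of array J, the count of runs and the selection of runs were chosen only after those results were seen; the tests of spot distance, of distance in ORF number, of centring, of brightness and of splits of the extracts were fixed before their values were seen.

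The cysteine effect differed between exponential and early stationary phase for 83 ORFs, by the test of the difference itself in limma. With array J kept, this count was 0 without array A and 6 without array B (502 and 444 ORFs at an unadjusted p under 0.05 in limma). No ORF passed when either CysExp extract was left out with array J kept, but some passed when array J was left out too. Each early stationary arm is 1 extract whose spread is taken from the exponential groups. The 83 ORFs included 6 runs of neighbouring identifiers. The median difference of the effect, early stationary minus exponential, was -4.77 in a run of 5 ORFs, -1.74 in a run of 3, -1.33 in a second run of 3, -0.74 in another run of 3, 1.22 in a run of 4 and 0.69 in a second run of 5. Without array J all members passed in 5 of these runs, and none passed in the run of 3 ORFs at -1.74.

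Array J stood apart from the other 12 arrays. Its prediction error under its label was 0.556. A wrong extract in its Cy5 channel is a candidate explanation: if that channel held NoCysEarlySta F4, the error would be 0.141, inside the range of the other arrays. A failed hybridisation is argued against by the correlation of 0.936 between array J and that prediction. A real difference between NoCysExp F2 and F4 is argued against as the whole cause, since arrays A and B hold the same F2 extract and the error of array J under its label was 1.64 times the highest of the other arrays. The labels cannot settle the matter, and array J entered every comparison under its own label or not at all.

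Changed ORFs lay in runs of consecutive identifiers. Placement on the array is argued against: the median distance between spots of consecutive ORFs was 0.998 times that of random ORFs. The correlation of the exponential log2 changes fell from 0.639 at a distance of 1 in ORF number to 0.347 at 2, 0.210 at 5 and -0.0432 at 100. As a hypothesis, the identifiers may follow the order of the chromosome, with neighbours transcribed together as operons. Cross-hybridisation between neighbours was not tested, since no probe sequences were used here.

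In exponential phase, 108 of the 117 called ORFs were higher without cysteine. The loess curve is argued against as the source, since under median centring 90.8% of the calls were still higher. Both settings centre each array, so an effect of centring itself was not tested. Falls hidden among dim ORFs are argued against, since 92.3% of the 52 calls among ORFs brighter than the median were higher. The changes themselves were skewed: 61 ORFs had a log2 change of at least 1 and 4 of at most -1. With arrays as replicates, 425 ORFs were higher and 456 lower, so the imbalance was not seen among the longer list of calls that this setting makes. The absence of cysteine, the biological difference that the design names, stays open as untested. There are only 3 splits of the 4 exponential extracts into 2 and 2, too few for a share under 0.05: the real split gave 117 calls and was the only 1 of the 3 to give as many, and the highest of the others gave 0.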

How the results depend on the processing

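Settings combined with the removal of array J, the use of unflagged spots and that of the direct arrays alone were chosen after seeing the data. Counts follow the order exponential medium, early stationary medium, mean phase, phase with cysteine, phase without cysteine and difference of medium effects, for which all arrays gave 117, 221, 602, 698, 1 and 83. For counts that moved by over 1.5 times the cause was not tested, except that fewer extracts leave fewer degrees of freedom and a minimum change removes calls by construction.

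With no background subtraction the medium counts were 52 and 108 and the difference count 16 (5 higher and 11 lower, against 37 and 46). Median centring gave 4 for the phase without cysteine (3 higher and 1 lower), and the mean over probes gave 0 there (335 at an unadjusted p under 0.05 in limma). No dye effect gave 23 for the difference. The deposited values gave 0 for the phase without cysteine (332 unadjusted) and 147 for the difference (83 higher and 64 lower). A minimum change of 1 on the log2 scale gave 59, 44, 70 and 128 for the first 4 comparisons and 44 for the difference. Arrays as replicates, which measures only the spread between arrays, gave 881, 1140, 1299, 1362, 831 and 1083, and without array J 1034, 1308, 1366, 1422, 1102 and 1257. No other count moved by over 1.5 times under these settings, the filter on dim probes, the omission of array N or unflagged spots. The direct arrays alone gave 108 for the exponential medium. The Aquantile step leaves the log2 ratios unchanged, so its counts equal those of the main fit by construction and it tests nothing here.

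Leaving out each array gave 95 to 150, 88 to 264, 320 to 809, 506 to 831, 0 to 183 and 0 to 100. Leaving out each exponential extract gave 0 to 198, 6 to 274, 426 to 551, 540 to 677, 0 to 141 and 0 to 219, and with array J also left out 84 to 146, 149 to 422, 531 to 926, 639 to 842, 100 to 176 and 22 to 238 (907 for the mean phase without CysExp F1, 124 for the phase without cysteine without NoCysExp F4, and 38 for the difference without NoCysExp F2). The extracts share F numbers only between phases (F3 with cysteine, F4 without). With the F number as a block over these 2 pairs, limma called 1 ORF in the mean phase comparison (252 unadjusted), or 2 without array J (305 unadjusted); with 1 early stationary extract per medium, whether the numbers pair the extracts could not be checked, and no block was possible in the medium comparisons, which share no number.

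The 85 exponential calls in runs became 538 with arrays as replicates, 677 with that and without array J, and 44 without NoCysExp F4 and array J; other values stand with the result. The 4 named ORFs kept their direction in every setting run: the exponential log2 change was 3.04 to 6.69 for LR1RLRE00827, 3.02 to 6.67 for LR1RLRE00828, -2.98 to -1.92 for LR1RLRE01446 and -1.77 to -1.04 for LR1RLRE00774. None of the 4 passed in limma with no background subtraction (adjusted p 0.0582 to 0.154) or without CysExp F1 or F3 (0.119 to 0.202, and 0.0556 to 0.136 with array J also left out), and all 4 passed in the other settings. Agilent's processed signals, slide, scan date and the gene list tests were not run, since the files hold none of the first 3 and no ORF could be named. The median spot signal was 697 to 996 over a background of 485 to 507.5, so ORFs near background limit the folds.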

Other observations

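The test with split extracts reported here was fixed before its values were seen; the runs were picked after theirs.

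Runs of neighbouring ORFs not yet described moved in several ways. A run of 4 ORFs was higher without cysteine in both phases, by a median of 1.21 in exponential and 1.40 in early stationary phase, and its effect did not pass the test of a difference between phases (median difference 0.13). Among the ORFs higher without cysteine in early stationary phase, runs of 5 and 3 ORFs had medians of 0.75 and 0.89, and in exponential phase they stood at -0.03 and 0.08, where none passed; the difference between phases itself passed for 2 of the 5 and 2 of the 3. Among the lower ones, a run of 6 had a median of -0.66 and a run of 5 one of -0.56, with exponential values of -0.05 and 0.02; the difference passed for 1 of the 6, or 0 without array J, and 1 of the 5. Of the run of 6, 4 passed in early stationary phase without array J. It rose on entry into early stationary phase with cysteine, by a median of 0.92 with 5 of 6 called.

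ORFs that were higher without cysteine in exponential phase were often also higher in early stationary than in exponential phase with cysteine. Of the 108 and 389 such ORFs, 81 were shared, against 25.0 for independent lists, and 6 of the 108 were lower in the phase comparison. Without array J, 77 were shared, against 27.9. The common spread of each ORF in both tests can raise these overlaps too. The comparisons share the 2 CysExp extracts, and simulated unchanged groups gave a correlation of 0.366 and a covariance of 0.0172, against 0.546 and 0.166 observed. As a hypothesis, lack of cysteine may bring on in exponential phase part of the change that cultures with cysteine show later. Chance variation of the shared extracts as the only source is argued against: with 1 CysExp extract given to each comparison, the covariance was 0.159 in one split and 0.155 in the other. Without array J it was 0.143 and 0.116. In each split a comparison held a single CysExp extract, so these values have no replicate check. Both comparisons still subtract a CysExp level, so ORFs whose level is particular to the CysExp group would also give a positive covariance. The splits therefore do not test the hypothesis.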
